A study of Enchytraeus crypticus with 48 samples.

How the data were processed

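Gene expression was measured in whole bodies of Enchytraeus crypticus, a small soil-dwelling oligochaete worm, with a 1-colour oligonucleotide array. Per the labels, each sample was total RNA from 40 adult worms with a clitellum, kept for 5 days in reconstituted water with or without titanium dioxide particles, under laboratory light or UVA. The 48 arrays fall into 16 groups of 3, and the series' design text calls the 3 samples of a group biological replicates. Per the labels' protocols, RNA was amplified with a low-input kit, labelled with Cy3 and mixed with a spike-in kit, a set of foreign transcripts added to every sample. Groups, particle sizes, iron contents and concentrations were taken from the labels.

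The deposited scanner tables hold spot intensity on a linear scale, and per the file headers they were made with Agilent Feature Extraction 10.7.3.1. The column used was the processed signal, which that program had already corrected for background, per the file headers. Each array has 45167 spots, of which 1417 are control spots and 43750 are distinct worm probes. No probe carries a gene name or description: 23177 are named by an assembled contig and 20573 by a single sequencing read. No table pairing these sequences with genes was used here, so the gene lists on stress, iron, reproduction and other processes that were set before the data were examined are void, and no function is given for any probe. The deposited series table of intensity values holds the same processed signals. All 2100000 values compared lay within 0.6% of the scanner value when its rows were put in probe-name order, against 0.6% of them when matched on its row number. Those rows were therefore matched in probe-name order. Its scale is linear and its columns are not centred, so no question of scale, centring or direction stays open for it. No column was left without a sample.

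Between 10739 and 25345 probes per array were flagged well above background, and the median share over arrays was 39.65%. Only on 4 arrays were more probes above background than not. The log2 processed signal was therefore scaled by subtracting each array's 75th percentile over the 8498 probes well above background on all 48 arrays. All levels given in log2 units are on this scale. Of the probe values, 96 carried an outlier flag and were left out, and 0 were saturated. Probes well above background on at least 3 arrays were tested, which kept 27102 and left out the rest.

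Linear models were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 to all 48 arrays with 1 term per group, leaving 32 residual degrees of freedom. A probe was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. All tests are two-sided. Comparisons were each exposure against the control of its light, the 2 controls against each other, concentrations and particle types against each other, and the difference between the lights in the change with particles. The 3 direct comparisons of the lights at the same particle were chosen after seeing the data. The precision of every value is limited by the number of arrays, 3 per group. In comparisons of 2 groups the median standard error was 0.48 log2 units, and the median 95% interval reached 0.98 to either side, a 1.97-fold change. For the differences between lights these were 0.68 and 1.38.

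As the sequences have no names, at most 2 probes that were higher and 2 that were lower are named in each comparison. They are those with the largest fold among called probes whose 3 values in one group do not overlap the 3 in the other. The overlap condition was not applied to the differences between the lights, and where 5 or fewer probes were called all are named. Where a probe was well above background on none of the 3 arrays of the dimmer group, the fold is given as a bound. The bound sets the brighter group's mean against, per array, the higher of the dim probe's value and the lowest value of any probe well above background. Medians of changes over called probes, and their values in other settings, are of fitted changes and include probes with only a bound. With those at their bounds, or at no change where the bound was under 1-fold or both groups were below background, the medians of 1.35 to 1.98 log2 units in comparisons of 2 groups with over 5 calls became 0.92 to 1.74. Figures were drawn with matplotlib 3.10.9.

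The procedure was tested on simulated data for the comparison of pure 12 nm particles at 1 mg/L with the control under UVA, with 200 of 27034 probes changed. It recovered 22% of the probes changed 2-fold, 64% of those changed 4-fold and 82% of those changed 8-fold. None of those changed 1.5-fold were recovered, and 4 unchanged probes were called. The simulated noise was independent between probes, and a probe had the same spread in all groups. Recovery may therefore be lower where the replicates of a group spread more widely.

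Alternatives fixed before the data were examined were normexp background correction with an offset of 50, quantile normalization, no filter on dim probes, a filter requiring 24 arrays (16566 probes), slide as a fixed block, replicate number as a block, a fit of only the groups compared, the series table and leaving out each array. Normexp was planned on the mean spot signal, and the median signal was used because the tables hold no mean signal column. Chosen after seeing the data were a 75th percentile over all probes, scaling to 6 spike-in transcripts, array brightness as a covariate, slide as a random block, scan day as a block and a fit of the arrays of scan day 2. Brightness is the log2 of the 75th percentile subtracted in scaling. The arrays lay on 20 slides with at most 4 each and were scanned on 3 days, with 14, 20 and 14 arrays. All groups share replicate numbers 1 to 3, which were not used in the main design.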

Results

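The expression of 27102 probes was compared across 16 groups of Enchytraeus crypticus exposed for 5 days in water to titanium dioxide particles. Under laboratory light there were a control and 9 exposures: pure particles of 12 nm at 1 and 10 mg/L, of 27 nm at 10 mg/L and of 10 nm at 10 and 100 mg/L, and iron-containing particles with 2% iron (10 nm), 6% iron (5 nm) and 8% iron (5 nm) at 10 mg/L and with 10% iron (10 nm) at 1000 mg/L. Under UVA there were a control and 5 exposures: pure 12 nm at 1 and 10 mg/L, pure 27 nm at 10 mg/L, and 1% iron (11 nm) at 1 and 10 mg/L. Each group had 3 arrays of 40 pooled worms each. Between 24.5% and 57.9% of the probes on an array were well above background. The treatments had been selected, per the series' design text, from known effects on reproduction.

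The worms kept under laboratory light without particles stood apart from all other groups. Their 3 arrays lay above all 45 other arrays on 2954 probes and below them on 2864, where chance gives 1.6 on each side. The group with the next most such probes, 2% iron under laboratory light, had 34 above and 83 below. On the first principal component, which held 45.2% of the variance, this control averaged -227.9 ± 3.0 (SD, n = 3), the UVA control -62.9 ± 45.6, and the exposures with 8% iron and 2% iron under laboratory light 116.8 ± 12.3 and 115.5 ± 18.2. The read GYUW2K401EIO4R was well above background on all 3 arrays of each group named here. Its level was -1.42 ± 0.55 log2 units in the laboratory-light control, 6.31 ± 0.46 in the UVA control and 7.18 ± 0.54 with pure 27 nm particles under laboratory light.

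**Figure D1:**
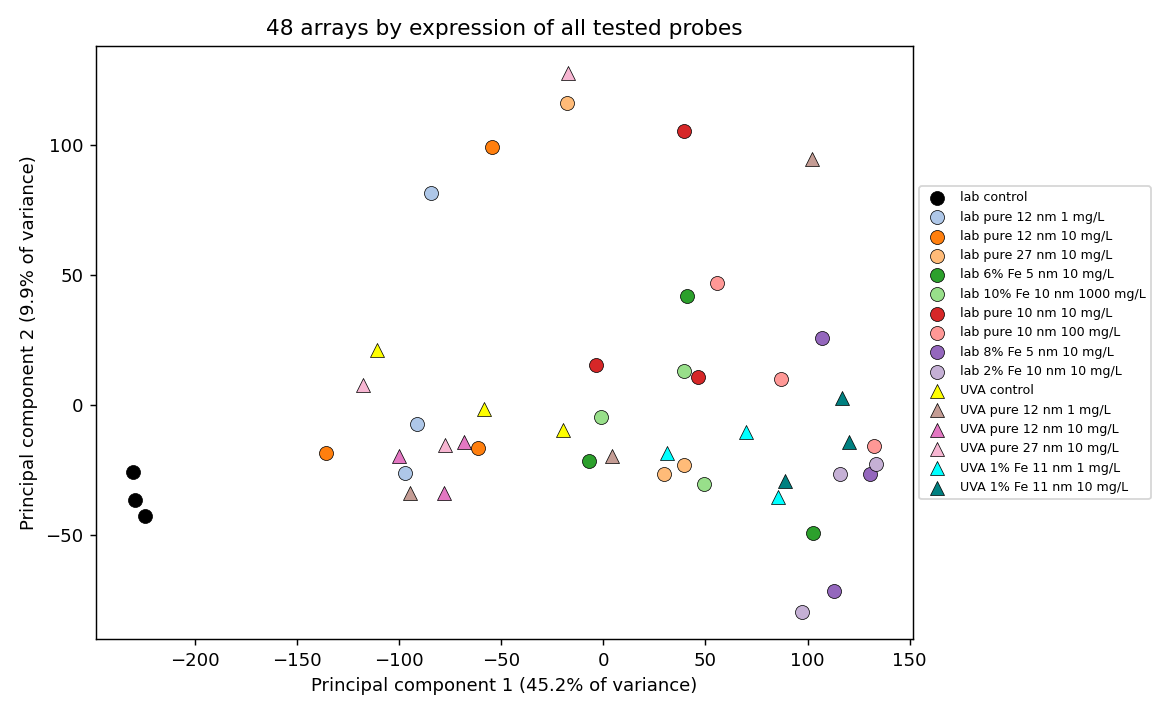
Each point is 1 of the 48 arrays on the first 2 principal components of the scaled log2 signal, with circles for laboratory light and triangles for UVA, and the share of variance on each axis. The 3 laboratory-light controls (black) lie at the far left, at a mean of -227.9 on the first component, and the groups with 8% iron and 2% iron lie at the right, at 116.8 and 115.5.

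The first question was what UVA did without particles. In the UVA control 3569 probes were higher and 3338 lower than in the laboratory-light control (limma). GYUW2K401A8W3P was at least 288-fold higher under UVA (adjusted p = 0.00053), at 0.61 ± 0.95 log2 units against a control not well above background on any of its 3 arrays. Contig contig14757 was higher too, at 0.60 ± 1.71 against -8.17 ± 1.19, a level that 1 of the 3 control arrays measured above background (adjusted p = 3.5e-07). Lower under UVA were GYUW2K402HWISX, at -7.67 ± 2.02 against 0.02 ± 0.39 (adjusted p = 1.1e-08), and contig05679, at -6.94 ± 1.84 against 0.73 ± 0.19 (adjusted p = 1.8e-09), both above background on 1 of 3 UVA arrays. In the 9 exposures under laboratory light the means of GYUW2K402HWISX were -8.87 to -7.45 and those of contig05679 -8.26 to -6.73. These low levels are thus not particular to UVA. In the same 9 exposures the means of GYUW2K401A8W3P were -3.85 to 1.38 and those of contig14757 -1.77 to 4.75. The high levels of these probes are thus not particular to UVA either. With slide as a fixed block 712 probes were called, as the median change of the called probes went from 1.69 to 1.39 log2 units and the median SE from 0.44 to 0.64, and with spike-in scaling 756 were higher and 8187 lower. Without UVA control replicate 3 the count was 4105. Within scan day 2 (1 UVA array against 3) 99.7% of the called probes kept their direction. These arrays were also in the fit that called the probes, so this says little about scan day. With scan day as a block 6803 were called, and the median change went from 1.69 to 1.70 log2 units (median SE 0.44 and 0.46).

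Under laboratory light, all 9 exposures differed from the control, on 5364 to 16075 probes. The fewest were called with pure 12 nm particles, 3439 higher and 1925 lower at 1 mg/L and 3352 higher and 2466 lower at 10 mg/L. Pure 27 nm particles at 10 mg/L gave 7046 higher and 5433 lower, and pure 10 nm particles gave 7752 and 5908 at 10 mg/L and 8933 and 7028 at 100 mg/L. The iron-containing particles gave 7864 higher and 8007 lower at 2% iron, 7067 and 6303 at 6%, 8294 and 7781 at 8%, and 6594 and 6278 at 10% iron and 1000 mg/L. In 1748 to 7068 of the calls 1 group or both were not well above background on any array, so their folds depend on the floor. The median fitted change of a called probe lay between 3.35-fold and 3.82-fold in the 9 exposures, and between 2.32-fold and 2.53-fold with such probes at their bounds.

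**Figure D2:**
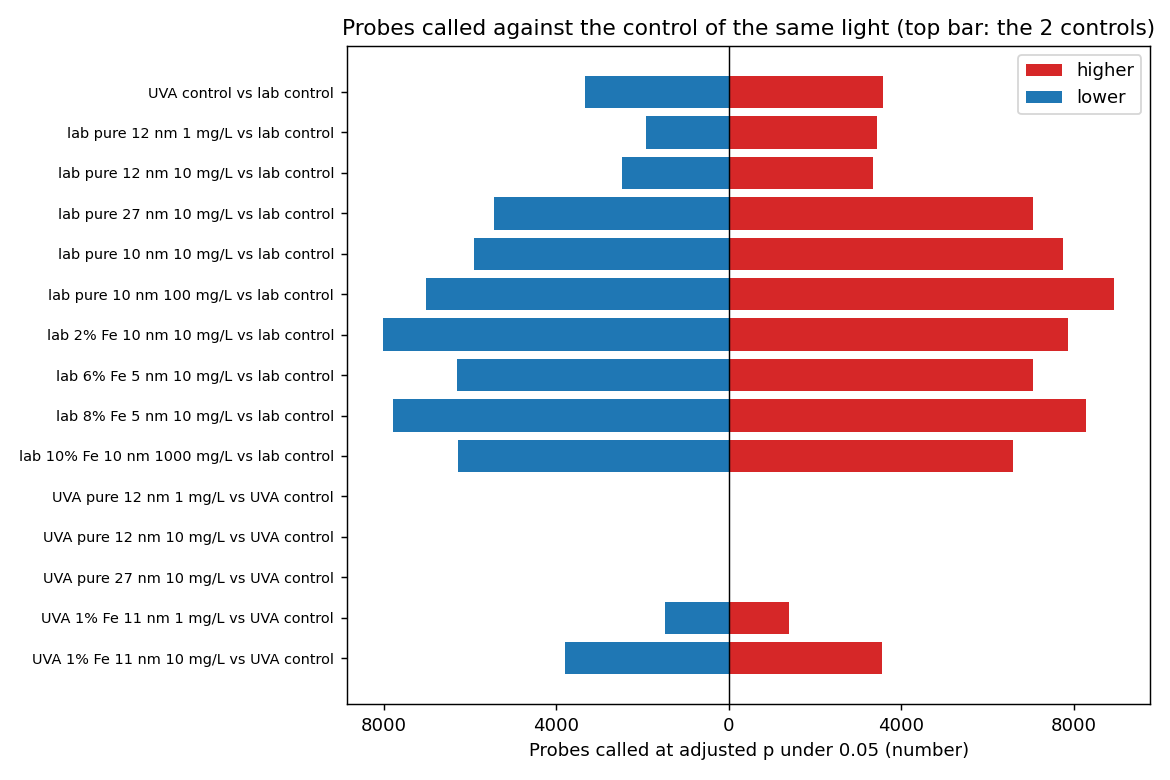
Bars give the number of probes called higher (right, red) and lower (left, blue) than the control of the same light at an adjusted p under 0.05, and the top bar compares the 2 controls. All 9 exposures under laboratory light have bars on both sides, from 5364 to 16075 probes in all, while the 3 pure-particle exposures under UVA have none.

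Much of the change ran the same way in the 9 exposures. Of 20973 probes called in at least 1 of them, 2140 were higher and 1483 lower in all 9, and 64 were called in both directions. Correlations of log2 changes over probes (which are not independent replicates) between pairs of these exposures ranged from 0.80 to 0.98 with a median of 0.93, where unchanged groups simulated against a shared control gave 0.50. The covariance ranged from 1.35 to 4.53 against a simulated 0.15. The simulated noise was independent between probes, which makes these simulated values a weak yardstick. Between pure 10 nm at 100 mg/L and 8% iron 7556 higher and 6689 lower calls were shared, where independent lists share 2734 and 2018. All pairs used the same 3 controls and none was computed with separate ones, so part of the excess may come from the shared controls.

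Several probes had the largest changes in more than 1 exposure. With 2% iron, contig14757 reached 4.75 ± 0.04 log2 units (adjusted p = 1.9e-11), and contig24448 was at least 1780-fold higher (adjusted p = 1.7e-11). With 8% iron these were 4.32 ± 0.83 (adjusted p = 4.4e-11) and at least 1640-fold (adjusted p = 2.5e-11), with 6% iron 2.79 ± 1.78 (adjusted p = 1.4e-09) and at least 554-fold (adjusted p = 9.4e-10), and with 10% iron 1.40 ± 1.80 (adjusted p = 2.2e-08) and at least 221-fold (adjusted p = 1.5e-08). Pure 10 nm particles at 100 mg/L brought contig14757 to 3.23 ± 1.62 (adjusted p = 4.3e-10) and contig24448 at least 797-fold up (adjusted p = 2.5e-10). At 10 mg/L contig14757 stood at 1.25 ± 1.29 (adjusted p = 3.9e-08) and GYUW2K401A8W3P was at least 492-fold higher, at 1.38 ± 3.59 (adjusted p = 9.1e-05). That bound allows for the floor and not for this wide spread. With pure 27 nm particles GYUW2K402HKE0W was at least 311-fold higher (adjusted p = 8.5e-10), and in the 12 nm groups at least 117-fold at 1 mg/L (adjusted p = 5.2e-08) and 179-fold at 10 mg/L (adjusted p = 1.2e-08).

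Among probes that were lower, contig00196 was at least 365-fold lower with 10% iron (adjusted p = 3.8e-09), at least 210-fold with pure 10 nm at 10 mg/L (adjusted p = 1.5e-08) and at least 186-fold at 100 mg/L (adjusted p = 4.1e-09). Its control level was 1.72 ± 0.08 log2 units. With 8% iron contig03802 was at least 686-fold lower (adjusted p = 1.9e-10). Contig contig05679 was at least 158-fold lower with 6% iron (adjusted p = 2e-11) and at least 185-fold with 10% iron (adjusted p = 2.7e-11), and with pure 12 nm at 1 mg/L it was at -7.00 ± 0.96, measured on 2 of 3 arrays (adjusted p = 1.3e-09). GYUW2K402F73VR fell from 3.97 ± 0.09 in the control to -5.76 ± 0.83 with 2% iron (adjusted p = 1.5e-10), a level above background on 1 of 3 arrays.

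**Figure D3:**
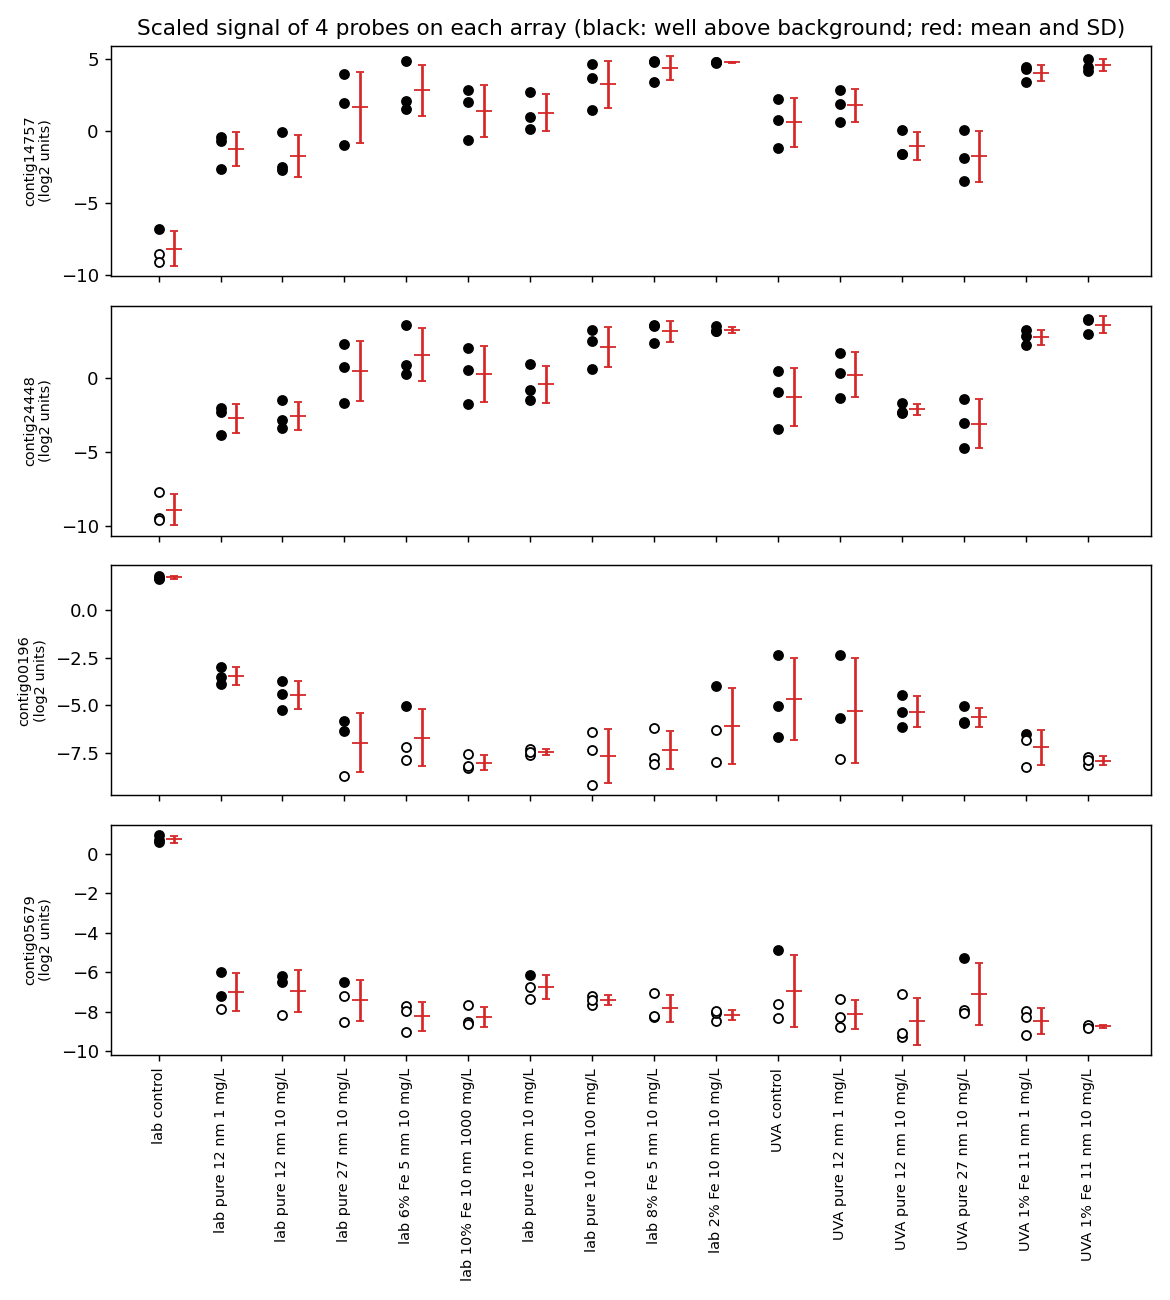
Each panel gives the scaled signal in log2 units of 1 probe on all 48 arrays by group, black where it was well above background and white where it was not, with the group mean and SD in red (n = 3). The contigs contig14757 and contig24448 are lowest in the laboratory-light control, where the second was not well above background on any array, and contig00196 and contig05679 are highest there, at 1.72 and 0.73.

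The laboratory-light counts depended on slide, brightness and scaling. With slide as a fixed block 376 probes were called with pure 10 nm at 10 mg/L, 478 with pure 12 nm at 1 mg/L, 2034 with pure 27 nm, 3135 with 2% iron and 10645 with 6% iron. With array brightness as a covariate the 9 counts lay between 3096 and 9364. The median change of the called probes, 1.74 to 1.93 log2 units over the 9 exposures (median SE 0.44 to 0.47), was 1.29 to 2.08 with slide (0.48 to 0.80) and 1.33 to 1.61 with brightness (0.48 to 0.64). The 5364 calls of pure 12 nm at 1 mg/L were 3555 and 3570 without laboratory-light control replicate 1 and 2, and the 5818 at 10 mg/L were 3704 without its own replicate 3. All 3 laboratory-light controls were scanned on day 2, and within that day 2% iron, with 3 arrays, called 15716 probes. Between 49.5% and 64.1% of the calls in these exposures were higher, against 2.4% to 19.9% when arrays were scaled to the spike-ins and 80.5% to 87.2% after normexp.

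The signal of the worm probes relative to the spike-ins moved with the groups. It was -0.55 ± 0.16 log2 units in the laboratory-light control, -1.61 ± 0.45 in the UVA control and -3.97 ± 0.08 with 2% iron under laboratory light (SD, n = 3). Scaled to the spike-ins, the median log2 change over all tested probes between 2% iron and the control was -3.29, against at most 0.31 on either side for any comparison in the main scaling. Over the 48 arrays this signal correlated with the first component at Pearson's r = -0.89 (permutation p = 1e-05, adjusted 2.5e-05 over 10 relations) and Spearman's rho = -0.90 (permutation p = 1e-05), the smallest p that 100000 resamples can give. Without the 2 farthest arrays r was -0.87, within the scan days it was -0.87, -0.92 and -0.91 (permutation tests), and for deviations from the group means it was -0.58. The permutations over the 48 arrays shuffled them freely, so their p-values count replicates of a group as independent arrays. The percentile within this signal was also subtracted from every probe in scaling. For probes near the floor this ties the signal to the first component by construction.

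**Figure D4:**
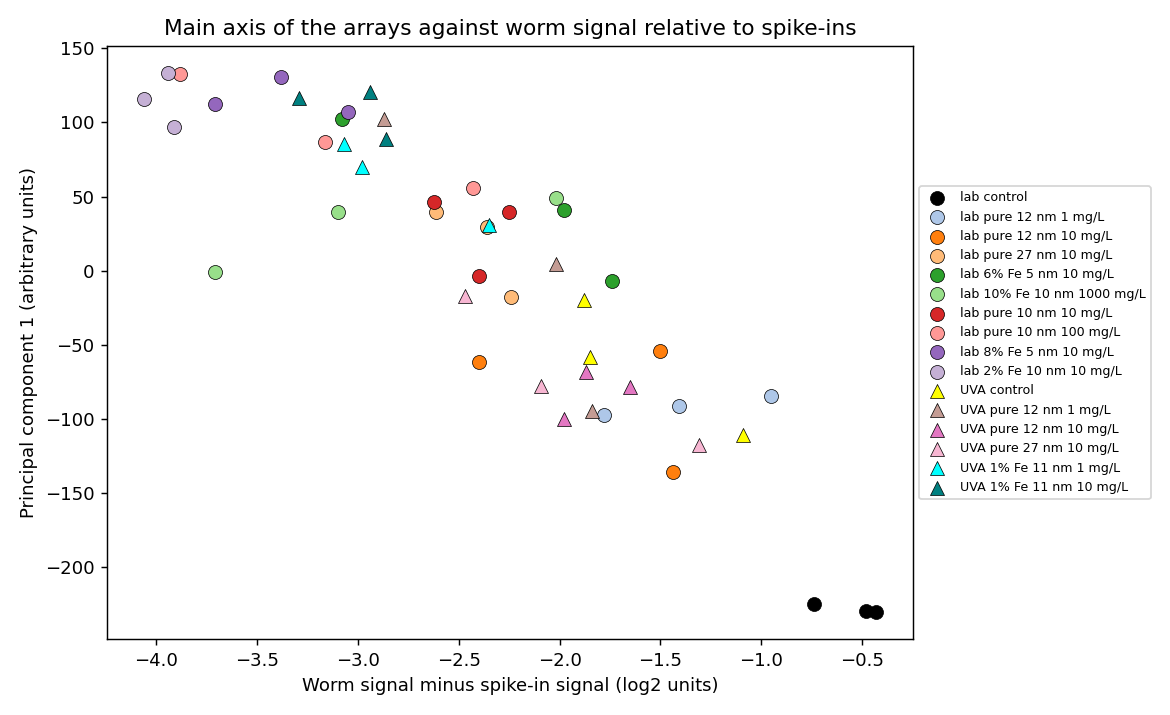
Each point is 1 of the 48 arrays, with the log2 signal of worm probes minus that of 6 spike-in transcripts on the horizontal axis and the first principal component (arbitrary units) on the vertical axis. The laboratory-light controls (black) lie at the lower right, at a mean of -0.55 log2 units, and the 2% iron arrays at the upper left, at -3.97.

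Under UVA, no probe was called with pure particles against the UVA control (limma). At an unadjusted p under 0.05 the share of probes was 7.3% with 12 nm at 1 mg/L, 4.2% with 12 nm at 10 mg/L and 4.4% with 27 nm at 10 mg/L. Few changes of 2-fold or less would be called at this number of arrays, so the counts of 0 do not show that nothing changed. Without replicate 2 of pure 12 nm at 1 mg/L 1166 probes were called, and without replicate 1 there were 2. The first component of that group had an SD of 98.4, the largest of the 16 groups.

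Particles with 1% iron did differ from the UVA control. At 1 mg/L 1389 probes were higher and 1470 lower, and at 10 mg/L 3565 were higher and 3804 lower. Contig contig24448 was 16.7-fold higher at 1 mg/L (adjusted p = 0.016) and 30.2-fold higher at 10 mg/L (adjusted p = 0.00086), rising from -1.33 ± 1.98 log2 units in the control to 2.73 ± 0.51 and 3.58 ± 0.57. At 10 mg/L contig25159 was at least 19.6-fold lower (adjusted p = 0.00013) and GYUW2K401C8BAU at least 8.99-fold lower (adjusted p = 0.00013), and GYUW2K402F358Q was higher, at -0.82 ± 0.55 against -5.75 ± 1.62 measured on 2 of 3 control arrays (adjusted p = 0.0021). At 1 mg/L GYUW2K402F061M was at least 4.23-fold higher (adjusted p = 0.024), while GYUW2K402F73VR was 15.7-fold lower (adjusted p = 0.012) and contig12118 was lower, at -7.16 ± 0.74 against -3.11 ± 1.52 (adjusted p = 0.0055).

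These calls turned or ended in some settings. After normexp 17903 probes were higher and 986 lower at 1 mg/L, and 19640 and 1659 at 10 mg/L, against 164 and 9748, and 385 and 12850, with spike-in scaling. With slide as a fixed block 0 probes were called at 1 mg/L and 1 at 10 mg/L, with array brightness as a covariate also 0 and 1, and a fit of only these groups called 1 at 1 mg/L. For the probes called at 1 mg/L, the median change of 1.47 log2 units (median SE 0.40) became 1.49 (0.70) with slide and 0.91 (0.44) with brightness, and at 10 mg/L 1.53 (0.41) became 1.61 (0.73) and 0.94 (0.48). At 1 mg/L the count was 0 without UVA control replicate 1, 1210 without its replicate 2, and 589 and 23 without replicates 2 and 3 of the exposure, and at 10 mg/L it was 3579 without UVA control replicate 1.

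Concentrations of the same particle were compared in 4 pairs, and no probe was called in any (limma). The share at an unadjusted p under 0.05 was 1.1% for pure 12 nm under laboratory light, 14.6% for pure 12 nm under UVA, 15.2% for pure 10 nm under laboratory light and 6.7% for 1% iron under UVA. Without replicate 2 of pure 12 nm at 1 mg/L the UVA pair gave 2419 calls, and without replicate 1 of the 100 mg/L group the pure 10 nm pair gave 1123. The pure 10 nm pair also had calls with quantile normalization, the stricter filter, slide as a random block and scan day as a block, as listed below.

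Among pure particles at 10 mg/L under laboratory light, 787 probes were higher and 1557 lower with 10 nm than with 12 nm. Contig contig20237 was 27.0-fold higher (adjusted p = 0.0078), and contig02290 was at least 6.77-fold lower (adjusted p = 0.010). The call rested on single arrays: 0 probes were called without replicate 2 of the 12 nm group, 1102 without its replicate 1, and 1009 and 301 without replicates 2 and 3 of the 10 nm group, and 0 with slide as a fixed block. With that block the median change of the called probes fell from 1.56 to 0.32 log2 units (median SE 0.43 and 0.68). Between 27 nm and 12 nm particles no probe was called under either light (limma), with 16.6% of probes at an unadjusted p under 0.05 under laboratory light and 3.8% under UVA. Without replicate 3 of the 27 nm group the laboratory-light count was 1510.

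Particles that differ in iron were compared at 10 mg/L. With 2% iron 1342 probes were higher and 2116 lower than with pure particles of the same 10 nm size. GYUW2K402HHKW8 was at least 5.90-fold higher (adjusted p = 0.00097) and contig00597 at least 4.39-fold lower (adjusted p = 0.0058). With slide as a fixed block 1495 were called, 60.4% of them higher, and the median change of the probes called in the main fit went from 1.35 to 1.33 log2 units (median SE 0.37 and 0.44). The share of higher calls, 38.8%, became 67.4% after normexp, 66.3% with a percentile over all probes, 1.0% of 19398 calls with spike-in scaling and 60.8% of 581 in a fit of only these groups. The count was 1081 and 1617 without replicates 1 and 3 of the pure group, and 2297 and 1435 without replicates 1 and 3 of the iron group.

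With 8% against 6% iron, both 5 nm, 14 probes were higher and 153 lower. Contig contig22745 was at least 2.36-fold higher (adjusted p = 0.039) and contig14934 at least 1.52-fold lower (adjusted p = 0.046). The count ranged from 5 to 1633 as each of the 6 arrays was left out, and every one of these 6 counts lay over 1.5 times from 167. A fit of only these groups called 0, as did slide as a fixed block, with which the median change of the called probes went from 1.46 to 1.13 log2 units and the median SE from 0.33 to 0.65.

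Under UVA, 1% iron of 11 nm gave 4408 higher and 3977 lower probes than pure 12 nm at the same 10 mg/L. Contig contig20433 was 54.0-fold higher (adjusted p = 0.00011), at 1.70 ± 0.78 log2 units against -4.05 ± 0.82, and contig12118 was at least 12.6-fold lower (adjusted p = 4.2e-05). Contig contig25159 was at least 15.5-fold lower (adjusted p = 1e-04). No probe was called with slide as a fixed block: the median change of the called probes went from 1.57 to 1.23 log2 units and the median SE from 0.42 to 0.82. Without replicate 1 of the pure group the count was 5512, and with spike-in scaling 582 were higher and 8572 lower.

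The change with particles differed between the lights. For pure 12 nm at 1 mg/L the difference was called on 1022 probes. The log2 change under UVA minus that under laboratory light was positive on 347 of them and negative on 675, for 12 nm at 10 mg/L on 753 and 1496, and for 27 nm at 10 mg/L on 3248 and 3406. For GYUW2K401EIO4R the change at 12 nm and 1 mg/L was lower under UVA by 7.26 ± 0.43 (SE) log2 units (adjusted p = 7e-14). Its levels were 6.87 ± 0.32 and 6.31 ± 0.46 with and without particles under UVA, and 6.40 ± 0.27 and -1.42 ± 0.55 under laboratory light. The counts were 69, 53 and 12 with slide as a fixed block: median changes went from 2.42 to 1.97, 2.49 to 2.01 and 2.30 to 1.61 log2 units, and median SEs from 0.57 to 0.76, 0.64 to 0.87 and 0.63 to 1.12. The share of positive differences, 34.0%, 33.5% and 48.8%, was 64.9%, 69.9% and 12.8% after normexp and 52.0%, 68.2% and 92.7% with spike-in scaling. Without UVA control replicate 3 the counts were 560, 1143 and 4350, and within scan day 2 the count for 27 nm was 1677, with 1 array each of the UVA control and of 27 nm under laboratory light.

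Compared directly at the same particle, few probes were called between the lights. For 12 nm at 1 mg/L 13 probes were higher and 60 lower under UVA, with 19.5% at an unadjusted p under 0.05 (limma). For 12 nm at 10 mg/L none was called (limma; 2.7% at an unadjusted p under 0.05). For 27 nm at 10 mg/L, with 13% at that p, 5 were higher. Those 5 were GYUW2K401EOKCI at 3.20-fold, contig00706 at 4.21-fold and GYUW2K402ILGVG at 3.65-fold, with contig11049 at least 1.54-fold, and GYUW2K402I73Y8 measured on 1 of 3 laboratory-light arrays, all at an adjusted p of 0.042. After normexp the fitted changes of the last 2 turned (adjusted p = 0.57 and 0.48). The count of 73 became 0 without any 1 of the 3 laboratory-light arrays and 4272 without replicate 2 of the UVA group, 4 and 22 without its replicates 1 and 3. It was 0 with slide as a fixed block: the median change of the 73 went from 1.98 to 1.30 log2 units and the median SE from 0.42 to 0.59. The count of 5 became 761 without replicate 3 of the laboratory-light group, between 0 and 22 without each other array, 0 with slide as a fixed block and 243 within scan day 2 (2 UVA arrays against 1).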

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

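The tests of slide, scan day and particles, and the test of the laboratory-light control alone, were chosen after their results were seen, as was the demand that a verdict hold with each array left out. The limits for brightness and for iron were set beforehand.

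The change with particles differed between laboratory light and UVA, by a test of the difference itself, on 1022 probes for pure 12 nm at 1 mg/L, 2249 for 12 nm at 10 mg/L and 6654 for 27 nm at 10 mg/L. A candidate explanation is the laboratory-light control alone, since it enters all 3 differences, and under 10% as many calls between the lights at the same particle was taken as its mark. At 27 nm this share was 0.075%, but 0 to 11% with each array left out. For 12 nm it was 7.1% at 1 mg/L (0 to 420%) and 0 at 10 mg/L (at most 0.097%). Only for 12 nm at 10 mg/L did the share stay under the limit, so whether that control alone made these differences stays open, and a response to particles that UVA altered stays open with it.

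The laboratory-light control stood apart from all 9 exposures under the same light. With brightness as a covariate the changes of the called probes kept a median slope of 0.84 on the unadjusted ones (0.77 to 0.89 with each array left out), above the limit of 0.5. A linear effect of brightness of the size seen among replicates is thus argued against as the whole cause. That fit takes the effect from replicates of a group alone. Mean brightness was 11.08 in this control and 9.34 to 10.41 in the exposures, so a larger effect of brightness between groups stays open. With slide as a fixed block the median slope was 0.87 (0.75 to 0.97), but only 10% iron, with 1 array, shared a slide with these controls. On that slide its called probes had a slope of 0.91 on the main changes, and 99.4% kept their direction, though both arrays also helped to call these probes. The other exposures were linked to the slides of the controls only through other groups, so slide stays open for them. For 2% iron, scan day is argued against by 15716 calls within day 2 (13282 to 14520 with 1 of these 6 arrays left out), against 15871 over all arrays. Both pure 12 nm groups had no array on that day, and the other exposures had fewer than 2% iron had. Scan day therefore stays open for them. The particle-free UVA control lay 70.7% of the way from this control to the mean exposure, with arrays at -110.7, -58.2 and -19.9 on the first component. Because its light differed too, particles and an unrecorded difference in how the laboratory-light control worms were kept or sampled, which no test bears on, cannot be told apart.

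Particles with 1% iron differed from the UVA control while pure particles under UVA were not called against it, and the direct comparison of iron with pure particles at 10 mg/L called 8385 probes. Slide as a fixed block left the changes at 10 mg/L at a slope of 1.08 (0.97 to 1.45 with each array left out). Their calls ended because the median standard error rose from 0.41 to 0.73 while the median change went from 1.53 to 1.61 log2 units. Slide cannot be judged by this fit. The 10 mg/L iron group shared a slide with only 1 array of another group, pure 12 nm at 1 mg/L under laboratory light. Without that array, the fit that gave 1.45, no slide links the iron group to the control. Brightness stays open: with it as a covariate the slope was 0.63, but 0.49 to 0.72 with arrays left out, and the median change fell from 1.53 to 0.94 with a standard error of 0.41 before and 0.48 after. In the direct comparison with pure particles the slope was 0.88 with this covariate. There the median change went from 1.57 to 1.39 log2 units, and 6155 of the 8385 probes stayed called. Leaving arrays out was not tried for that slope. A response to iron stays open too: over probes, the change from pure to iron particles under UVA correlated at 0.57, 0.23 and 0.64 with the 2%, 6% and 8% iron changes from pure 10 nm under laboratory light, and at 0.66 and 0.75 with the iron-free changes from 12 nm to 10 nm and to 27 nm. The planned difference, 0.57 less 0.66, was -0.09 (-0.19 to 0.03 with each array left out). Its iron-free side is a weak yardstick, as slide as a fixed block cut that change to a slope of 0.25 with 79.4% of probes keeping their direction. The pure 10 nm arrays enter the 2 sides with opposite signs, so their noise moves the 2 correlations in opposite directions. The 6% and 8% iron particles were also smaller, at 5 nm, so those changes are not of iron alone.

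A signal outside the worm probes also moved: on 39 of the 45 arrays other than the laboratory-light controls, the spike-in level was above that of every laboratory-light control array, the highest of which was 11.83 log2 units. It averaged 11.63 ± 0.28 in that control and 13.63 ± 0.10 with 2% iron (SD, n = 3).

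With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The 10 comparisons with the laboratory-light control called 5364 to 16075 probes as labelled, in 1 of 10 splits, and at most 2 in any other. Every other split mixes the 2 groups, so a large difference between them enters the spread and lowers the counts. Low counts in other splits, here and in the pairs below, are therefore little evidence on the labels. As labelled and in the highest other split, the counts were 2859 and 0 for 1% iron at 1 mg/L against the UVA control, 7369 and 0 at 10 mg/L, 8385 and 0 for 1% iron against pure 12 nm, 3458 and 12 for 2% iron against pure 10 nm, 2344 and 40 for 10 nm against 12 nm, and 167 and 10 for 8% against 6% iron. Directly between lights they were 73 and 3 for 12 nm at 1 mg/L, and 5 and 8 for 27 nm, as large in 2 of 10 splits. Where 0 probes were called all 10 splits were as large, with at most 2398 for pure 12 nm at 1 mg/L against the UVA control, 1 at 10 mg/L and 37 for 27 nm. The highest was 458 for the concentrations of pure 10 nm, 5 for those of 12 nm under laboratory light, 0 under UVA and 6 for 1% iron. It was 14 for 27 nm against 12 nm under laboratory light, 1 under UVA and 4 for the lights at 12 nm and 10 mg/L. The 2398 came from joining replicates 1 and 3 of the exposure with UVA control replicate 3. That split points to a structure of the samples, and it keeps on one side the only 2 of the 6 arrays that share a slide. With slide as a fixed block this split called 0, as the median change of its probes went from 1.41 to 1.14 log2 units and the median SE from 0.38 to 0.69, so slide is not shown to have made it. The splits with 458 and 37 keep 2 of 4 pairs of arrays of one scan day together, and with scan day as a block they called 253 and 103. With slide as a fixed block they called 0 and 24. Their median changes then went from 1.58 to 1.55 and from 1.58 to 1.93 log2 units, and median SEs from 0.39 to 0.57 and from 0.34 to 0.46. For the differences between the lights, the order being 12 nm at 1 mg/L, 12 nm at 10 mg/L and 27 nm, among 100 splits of treated and control arrays within each light, the labels included, 9, 4 and 6 called as many probes, with at most 6083, 4032 and 10989 in another split. Splits that mixed the laboratory-light groups called at most 1, 8 and 2, and all as large were among the 11, 10 and 8 that kept them apart, too few for a share under 0.05. Among those, joining UVA arrays otherwise gave more calls in some splits and fewer in others, so these counts do not set the labels of the UVA arrays apart.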

How the results depend on the processing

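The brightness, spike-in, scan-day, random-block and all-probe percentile settings, and the direct comparisons of the lights, were chosen after the results were seen. Counts below are of called probes that moved by over 1.5 times. Exposures are named by light, size or iron and mg/L and are set against the control of that light unless another group follows, "difference" is that between lights, and "light" a direct comparison. The cause of a move was not tested, except that fixed slide blocks leave 13 residual degrees of freedom and a fit of only the groups compared has fewer arrays. Slide as a fixed block gave 712 for UVA control, 478 for lab 12 nm 1, 2692 for lab 12 nm 10, 2034 for lab 27 nm 10, 376 for lab 10 nm 10, 7247 for lab 10 nm 100 and 3135 for lab 2% iron 10. Slide as a fixed block also gave 5594 for lab 8% iron 10, 0 for UVA 1% iron 1, 1 for UVA 1% iron 10, 0 for lab 10 nm 10 on 12 nm 10, 1495 for lab 2% iron 10 on 10 nm 10, 0 for lab 8% iron 10 on 6% iron 10 and 0 for UVA 1% iron 10 on 12 nm 10. Slide as a fixed block further gave 69 for difference 12 nm 1, 53 for difference 12 nm 10, 12 for difference 27 nm 10, 0 for light 12 nm 1 and 0 for light 27 nm 10. Normexp gave 8903 for lab 12 nm 1, 15857 for lab 12 nm 10, 21501 for lab 27 nm 10, 21362 for lab 10 nm 10, 21067 for lab 6% iron 10, 21088 for lab 10% iron 1000 and 1 for UVA 12 nm 1. Normexp also gave 2 for UVA 12 nm 10, 1 for UVA 27 nm 10, 18889 for UVA 1% iron 1, 21299 for UVA 1% iron 10, 1 for UVA 12 nm 10 on 12 nm 1, 5 for lab 10 nm 100 on 10 nm 10 and 1164 for lab 10 nm 10 on 12 nm 10. Normexp further gave 1230 for lab 2% iron 10 on 10 nm 10, 0 for lab 8% iron 10 on 6% iron 10, 3957 for UVA 1% iron 10 on 12 nm 10, 649 for difference 12 nm 1, 16237 for difference 27 nm 10 and 3 for light 27 nm 10. Quantile normalization gave 3381 for lab 12 nm 1, 1 for UVA 12 nm 1, 102 for lab 10 nm 100 on 10 nm 10, 1 for UVA 1% iron 10 on 1% iron 1, 2 for lab 27 nm 10 on 12 nm 10, 34 for lab 8% iron 10 on 6% iron 10 and 567 for difference 12 nm 1. Quantile normalization also gave 1467 for difference 12 nm 10, 37 for light 12 nm 1, 3 for light 12 nm 10 and 2 for light 27 nm 10. Spike-in scaling gave 2885 for lab 12 nm 1, 10703 for lab 12 nm 10, 20456 for lab 10% iron 1000, 9912 for UVA 1% iron 1, 13235 for UVA 1% iron 10, 138 for lab 10 nm 10 on 12 nm 10 and 19398 for lab 2% iron 10 on 10 nm 10. Spike-in scaling also gave 7421 for lab 8% iron 10 on 6% iron 10, 250 for difference 12 nm 1, 699 for difference 12 nm 10, 5 for light 12 nm 1 and 1 for light 27 nm 10. Fitting only the groups compared gave 8453 for lab 12 nm 1, 1 for UVA 1% iron 1, 0 for lab 10 nm 10 on 12 nm 10, 581 for lab 2% iron 10 on 10 nm 10, 0 for lab 8% iron 10 on 6% iron 10, 380 for difference 12 nm 1 and 3470 for difference 12 nm 10. Fitting only the groups compared also gave 0 for light 12 nm 1 and 0 for light 27 nm 10. Brightness as a covariate gave 3096 for lab 12 nm 10, 4867 for lab 27 nm 10, 7180 for lab 10 nm 10, 5231 for lab 10 nm 100, 9364 for lab 2% iron 10, 7857 for lab 6% iron 10 and 6959 for lab 8% iron 10. Brightness as a covariate also gave 7095 for lab 10% iron 1000, 0 for UVA 1% iron 1, 1 for UVA 1% iron 10, 1303 for lab 10 nm 10 on 12 nm 10, 3 for lab 8% iron 10 on 6% iron 10, 3291 for difference 27 nm 10 and 29 for light 12 nm 1. Brightness as a covariate further gave 1 for light 12 nm 10 and 0 for light 27 nm 10. No filter on dim probes gave 26559 for lab 10 nm 10, 30082 for lab 10 nm 100, 29052 for lab 2% iron 10, 28965 for lab 8% iron 10, 1631 for UVA 1% iron 1, 2253 for lab 2% iron 10 on 10 nm 10 and 14 for lab 8% iron 10 on 6% iron 10. No filter on dim probes also gave 0 for light 27 nm 10. A percentile over all probes gave 2 for UVA 12 nm 10 on 12 nm 1, 1 for lab 10 nm 100 on 10 nm 10, 1392 for lab 10 nm 10 on 12 nm 10, 11 for lab 8% iron 10 on 6% iron 10, 9 for light 12 nm 1 and 0 for light 27 nm 10. Scan day as a block gave 1 for UVA 12 nm 10 on 12 nm 1, 42 for lab 10 nm 100 on 10 nm 10, 352 for lab 10 nm 10 on 12 nm 10, 13 for light 12 nm 1 and 0 for light 27 nm 10. The stricter filter gave 93 for lab 10 nm 100 on 10 nm 10, 2 for UVA 1% iron 10 on 1% iron 1, 3 for lab 27 nm 10 on 12 nm 10, 461 for lab 8% iron 10 on 6% iron 10 and 441 for light 12 nm 1. Slide as a random block gave 80 for lab 10 nm 100 on 10 nm 10, 491 for lab 10 nm 10 on 12 nm 10, 1 for light 12 nm 10 and 0 for light 27 nm 10. The replicate block gave 24 for lab 8% iron 10 on 6% iron 10, 45 for light 12 nm 1 and 0 for light 27 nm 10. Scan day 2 alone gave 1319 for UVA control, 7928 for lab 27 nm 10, 8060 for lab 6% iron 10, 3617 for UVA 12 nm 1, 127 for UVA 12 nm 10, 44 for UVA 27 nm 10 and 834 for UVA 12 nm 10 on 12 nm 1. Scan day 2 alone also gave 1454 for lab 10 nm 100 on 10 nm 10, 8 for UVA 27 nm 10 on 12 nm 10, 48 for lab 8% iron 10 on 6% iron 10, 1677 for difference 27 nm 10 and 243 for light 27 nm 10.

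Leaving out 1 array at a time gave 4105 to 7026 for UVA control, 3555 to 4090 for lab 12 nm 1, 3704 to 6066 for lab 12 nm 10, 0 to 1166 for UVA 12 nm 1, 0 to 3 for UVA 12 nm 10 and 0 to 2 for UVA 27 nm 10. The same procedure gave 0 to 3653 for UVA 1% iron 1, 3579 to 7157 for UVA 1% iron 10, 0 to 2419 for UVA 12 nm 10 on 12 nm 1, 0 to 1123 for lab 10 nm 100 on 10 nm 10, 0 to 1510 for lab 27 nm 10 on 12 nm 10 and 0 to 2140 for lab 10 nm 10 on 12 nm 10. It gave 0 to 6 for UVA 27 nm 10 on 12 nm 10, 1081 to 4194 for lab 2% iron 10 on 10 nm 10, 5 to 1633 for lab 8% iron 10 on 6% iron 10, 5512 to 7366 for UVA 1% iron 10 on 12 nm 10, 560 to 1202 for difference 12 nm 1 and 1143 to 3055 for difference 12 nm 10. It further gave 4350 to 7832 for difference 27 nm 10, 0 to 4272 for light 12 nm 1, 0 to 2 for light 12 nm 10 and 0 to 761 for light 27 nm 10. Most arrays whose loss moved a count are named beside it in the results. Of the others, difference 12 nm 1 was 664 and 650 without lab 12 nm 1 replicates 1 and 2, and difference 27 nm 10 was 4430 without UVA 27 nm 10 replicate 1. Difference 12 nm 10 was 1475 without lab control replicate 1, 1354 without lab 12 nm 10 replicate 3 and 1310 without UVA 12 nm 10 replicate 1. With any other array left out, a count of 0 rose to at most 6. In these fits and those of scan day 2, the spread is taken from all groups. Where scan day 2 has 1 array in a group, as in most of its comparisons, its counts do not separate the group from the array.

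The share of higher calls moved by over 10 points, among all scalings and among the other settings and left-out arrays with at least 100 calls, for UVA control from 51.7% to 71.9% with slide as a fixed block, 8.5% with spike-in scaling and 70.3% with scan day 2 alone; lab 12 nm 1 from 64.1% to 87.4% with slide as a fixed block; lab 10 nm 10 from 56.7% to 44.2% with quantile normalization and 77.6% with no filter; lab 10 nm 100 from 56.0% to 42.4% with quantile normalization and 76.6% with no filter; lab 2% iron 10 from 49.5% to 72.3% with no filter and 59.8% with the all-probe percentile; lab 8% iron 10 from 51.6% to 73.1% with no filter; UVA 1% iron 1 from 48.6% to 94.8% with normexp, 67.3% with the all-probe percentile, 1.7% with spike-in scaling and 35.8% with scan day 2 alone; UVA 1% iron 10 from 48.4% to 92.2% with normexp and 2.9% with spike-in scaling; lab 10 nm 10 on 12 nm 10 from 33.6% to 53.4% with no filter and 5.8% with spike-in scaling; lab 2% iron 10 on 10 nm 10 from 38.8% to 67.4% with normexp, 50.8% with quantile normalization, 60.4% with slide as a fixed block, 66.3% with the all-probe percentile, 1.0% with spike-in scaling and 60.8% with only the groups compared; lab 8% iron 10 on 6% iron 10 from 8.4% to 29.4% with quantile normalization and 45.5% with the all-probe percentile; UVA 1% iron 10 on 12 nm 10 from 52.6% to 6.4% with spike-in scaling; difference 12 nm 1 from 34.0% to 64.9% with normexp, 44.4% with quantile normalization, 17.0% with the stricter filter and 52.0% with spike-in scaling; difference 12 nm 10 from 33.5% to 69.9% with normexp, 46.3% with quantile normalization and 68.2% with spike-in scaling; difference 27 nm 10 from 48.8% to 12.8% with normexp and 92.7% with spike-in scaling; light 12 nm 1 from 17.8% to 5.4% with quantile normalization, 55.6% with the all-probe percentile and 0.0% with spike-in scaling; lab 27 nm 10 from 56.5% to 46.2% with scan day 2 alone; light 27 nm 10 from 100.0% to 65.0% with scan day 2 alone; lab 12 nm 10 from 57.6% to 46.8% without lab 12 nm 10 replicate 1; lab 8% iron 10 on 6% iron 10 from 8.4% to 24.1% without lab 6% iron 10 replicate 1; difference 12 nm 1 from 34.0% to 44.2% without UVA control replicate 1; light 12 nm 1 from 17.8% to 32.0% without UVA 12 nm 1 replicate 2; light 27 nm 10 from 100.0% to 51.1% without lab 27 nm 10 replicate 3. The results give the 9 laboratory-light exposures under spike-in scaling and normexp.

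In 0 of 28 comparisons did all 3 pairs of equally numbered samples have deviations from their group means that correlated above 0.1. Replicate numbers thus did not pair the samples, and the block on them, whose counts are those given above, moved no other count by over 1.5 times. The mean correlation of equally numbered samples of different groups was 0.00, as it was for differently numbered ones, against 0.17 for samples on the same slide. For the named probes, 1439 pairs of probe and setting kept their direction and side of the threshold and 226 lost the call. These probes were chosen as the largest called changes in the same data, which favours keeping the call. The pairs kept include 85 with the series table, which holds the same signals. Slide as a fixed block cost 45 pairs the call and left 40, and fitting only the groups compared cost 23 and left 62. In 2 pairs the direction turned: under normexp contig11049 moved to -0.16 and GYUW2K402I73Y8 to -0.18 in the comparison of the lights at 27 nm. The median correlation of exposures was 0.93 under laboratory light and 0.19 under UVA, and 0.91 to 0.97 and 0.13 to 0.43 in the 3 alternatives. Signal over background limits the dim probes: where a group had no array above background, folds of named probes are given as bounds, while fitted changes, such as that of contig11049, depend on the floor.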

Other observations

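The demand that a verdict hold with each array left out was chosen after the results were seen.

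The exposures under UVA correlated less with each other than those under laboratory light, a difference that was not tested. Their 10 pairwise correlations of log2 changes over probes had a median of 0.19 and ran from 0.03, for pure 12 nm and 1% iron at 10 mg/L, to 0.89, for the 2 concentrations of 1% iron, where unchanged groups simulated against a shared control gave 0.50. The covariance was 0.92 for the latter pair and 0.02 to 0.50 for the others, against a simulated 0.15. Most pairs fell under the simulated value. The simulated noise was independent between probes, unlike that of the replicates, so these simulated values are a weak yardstick for unchanged groups. The 2 concentrations of 1% iron shared 1280 higher and 1267 lower calls, against the same 3 control arrays. Pure 12 nm at 1 mg/L correlated at 0.72 and 0.73 with 1% iron at 1 and 10 mg/L although it had no calls of its own. The 2 lights are unlike sets here: pure particles had no calls under UVA, and all laboratory-light pairs shared a control that stood apart from every other group.

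A hypothesis is that the axis that parts the groups is a condition of the samples that the exposures do not set alone. If so, replicates of one group may differ along it as well. The first component of the replicate deviations within the 6 UVA groups, which held 38.1% of their variance, correlated over probes at an absolute r of 0.61 with the mean laboratory-light exposure minus its control, from other arrays, where 0.5 was the limit set before the value was seen. With each array left out it ran from 0.47 to 0.68, so it does not stay above the limit and the hypothesis stays open. The spread among replicates in pure 12 nm at 1 mg/L under UVA was the widest, with first components of 102.2, -94.5 and 4.3. Which condition this is was not tested, and because no probe has a gene name here, no tissue or process can be put to it.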
